A study of Mus musculus with 8 samples.

How the data were processed

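RNA was measured in lymph node cells that the submitters isolated by flow cytometry from naive B10.BR mice (3 arrays) and from mice 7 days (3 arrays) and 28 days (2 arrays) after immunization. Per the labels, 10 µg of total RNA, purified on columns, was made into biotin-labelled cRNA and hybridised to Affymetrix mouse arrays. The deposited table holds 22690 probe sets, with 0 missing values. The labels give no dates or batches and do not say whether replicates are separate animals. The number of arrays limits the precision.

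The deposited value is a linear ratio. The submitters' processing notes name GCRMA, with no version. Scaling per probe set is not stated and was read from the values: 47.9% of probe sets have a median over the 8 arrays of 1 (within 0.0015), and the highest median is 1. Each value was therefore taken as the GCRMA level divided by the probe set's median over the 8 arrays, or by a common floor where that median lies lower. The values run from 0.0153 to 117, and the median per array from 0.722 to 0.832. The choices made before the data were examined assumed levels on the log2 scale, with filters on level. Since ratios carry no level, those filters were replaced after the scale was seen, by a ratio of at least 1 on at least 2 arrays. This kept 13042 (57.6%) of the 22626 probe sets that are not controls. A stricter filter, a median of 1 over the 8 arrays, kept 10831.

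Values were analysed as log2 ratios with limma 3.58.1 in R 4.3.3. A single fit with 1 mean per group covered the 8 arrays, followed by empirical Bayes moderation. The comparisons were day 7 against naive, day 28 against naive and day 28 against day 7. Tests were two-sided, with Benjamini-Hochberg adjustment over the probe sets kept and a threshold of adjusted p under 0.05. The replicate number was not used as a block, since no label pairs the samples. Of the 22626 probe sets, 20380 carried 1 gene symbol, 691 several and 1555 none. Gene identifiers were matched to a RefSeq table for current names (20351 matched, 0 symbols changed), and coordinates were not used, since the arrays' genome build is not named. Each gene was represented by the kept probe set with 1 symbol, the highest median ratio over the 8 arrays and then the largest SD (7825 genes, of which 2610 had more than 1 kept probe set). Its adjusted p is that over all probe sets. The planned rule, the highest mean, assumed levels and was replaced after the scale was seen. Many probe sets share a median of 1, so the SD over these same arrays often decides. This favours the probe set that changed most and can enlarge folds and list medians.

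The genes named were set by a rule before the data were examined. It took, per comparison, the 10 largest rises and the 10 largest falls among genes past the threshold whose groups did not overlap. Chance gives no overlap for 10% of genes with 3 arrays against 3 and for 20% with 3 against 2. The rule also asked for a minimum level in the higher group, which was replaced by a mean log2 ratio of at least 0. Receptor segments and unnamed genes were not named. It also took up to 4 members with the smallest adjusted p, in the list's direction, of each gene list called, and a set of fixed markers, of which those analysed were Cd4, Cd8a, Cd3e, Cd44, Il7r, Ccr7, Cxcr5, Bcl6, Foxp3 and Mki67.

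Gene lists, 31 in all, were written before the data were examined. They cover T cell identity, CD8 T cell and cytotoxic, naive and resting T cell, T cell activation, follicular helper T cell, Th1 helper, Th2 helper, Th17 helper, regulatory T cell, DNA replication, mitosis, glycolysis, oxidative phosphorylation, cholesterol synthesis, interferon response, immediate early genes, heat shock, nucleolus and ribosome biogenesis, cytosolic ribosome, endoplasmic reticulum stress and secretion, apoptosis regulators, migration receptors, B cell, germinal centre B cell and plasma cell, antigen presentation (MHC class II), monocyte and macrophage, dendritic cell, neutrophil, NK cell, erythroid and platelet, and stroma and endothelium. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 30 lists with at least 5 members measured; stroma and endothelium, with 4, was described only. Camera compares a list with all other genes, so a list can be called with few members past the threshold. Of the lists called, 2 of 10 at day 7 against naive, 2 of 13 at day 28 against naive and 3 of 10 at day 28 against day 7 were also called with an estimated correlation, and 7, 4 and 7 by fry. Median, mean and camera direction had the same sign in all lists called, and differed in 3, 1 and 6 of the lists not called.

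Alternatives tried were no filter and the stricter filter, quantile normalization, median centring, trended and robust variance, only the 2 groups compared, array weights, a replicate block, a fold threshold of 2, adjusted p under 0.01, the mean of a gene's probe sets and leaving out each array. A term for the arrays of low against high spike-in signal, from 14 control probe sets, was added after seeing the data, as were shifts inside each of those sets. Naive replicate 1 is the only naive array of low signal. For day 28 against naive the term is therefore the same fit as leaving out that array. For day 7 against naive it sets the day 7 arrays against that array alone. Where 1 day 28 array was left out, the other was assumed to vary like the other groups. The genes shared by 2 comparisons were compared with 100 simulations of unchanged groups with the same shared naive arrays.

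The procedure was tested on simulated data with 50 changed probe sets per size and comparison among 13042. At 2-fold, 0% were recovered in each comparison. At 4-fold 34%, 32% and 28% were recovered, at 8-fold 66%, 58% and 56%, and at 16-fold 82%, 72% and 68%, for day 7 against naive, day 28 against naive and day 28 against day 7. Unchanged probe sets called numbered 6, 3 and 2. In 20 simulated sets, 2 of 1800 tests on unchanged lists were called, and a raised mitosis list was called in 20. The simulated noise was independent between probe sets, with no correlation between genes and no batch. These numbers therefore do not give the rate of false list calls on the real arrays.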

Results

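RNA of lymph node cells sorted by flow cytometry from B10.BR mice, an inbred strain, was measured on Affymetrix mouse arrays at 3 stages: in naive mice (3 arrays), 7 days after immunization (3 arrays) and 28 days after immunization (2 arrays). The labels name neither the immunogen nor the sorted population. They do not say whether replicates came from separate animals, so the p-values measure the spread between these arrays. Values are log2 ratios to each probe set's own median over the 8 arrays, or to a common floor, so 0 marks that median, or the floor where the median lies below it, and levels of different genes cannot be compared. For genes near background, folds understate the change in RNA. For genes with several probe sets, the one shown was often the one that varied most, which can overstate the change. Of 22626 probe sets without controls, 13042 were tested, representing 7825 genes.

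The arrays did not separate by group alone. Naive replicate 1 lay at -44.5 on the first principal component (43.7% of the variance), near the day 7 arrays (-71.7 to -55.4), whereas naive replicates 2 and 3 lay at 64.5 and 85.4 and the day 28 arrays at 35.2 and 44.3. The hybridisation spike-in controls, bacterial transcripts added to every sample, split the same way. Their median log2 ratio was -1.29 on naive replicate 1 and -1.88, -1.12 and -1.38 on the day 7 arrays. It was 0.92 and 0.75 on naive replicates 2 and 3, and 1.53 and 0.65 on the day 28 arrays. These are called the low and the high spike-in arrays, and shifts computed inside each set are given beside the gene groups. The log2 difference between 3' and 5' probe sets of Gapdh, a sign of RNA quality, was 0.54, 0.17 and 0.57 on the naive arrays, -1.04, -1.18 and 1.17 at day 7, and -1.09 and 0.02 at day 28. Since each probe set is scaled on its own, its sign does not tell which end had more signal, and only arrays can be compared. Beta-actin, given under other observations, did not order the arrays alike. Xist, the RNA that silences 1 X chromosome in females, had log2 ratios of -5.25, -5.58 and -2.17 on the naive arrays, 1.84, 0.98 and 1.48 at day 7, and -5.29 and 0.83 at day 28, by 1 of its 2 tested probe sets; the other ran from -3.41 on day 28 replicate 1 to 1.95 on day 7 replicate 3. The Y-linked gene Eif2s3y had log2 ratios of 2.87 on naive replicate 1 and 3.70 on day 28 replicate 1, and between -0.59 and 0.24 on the other arrays. Kdm5d, also Y-linked, had 3.35 on naive replicate 1 and between -0.66 and -0.29 on all other arrays, day 28 replicate 1 included, by 1 of 3 probe sets, all too dim to be tested; the other 2 did not set naive replicate 1 apart.

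**Figure D1:**
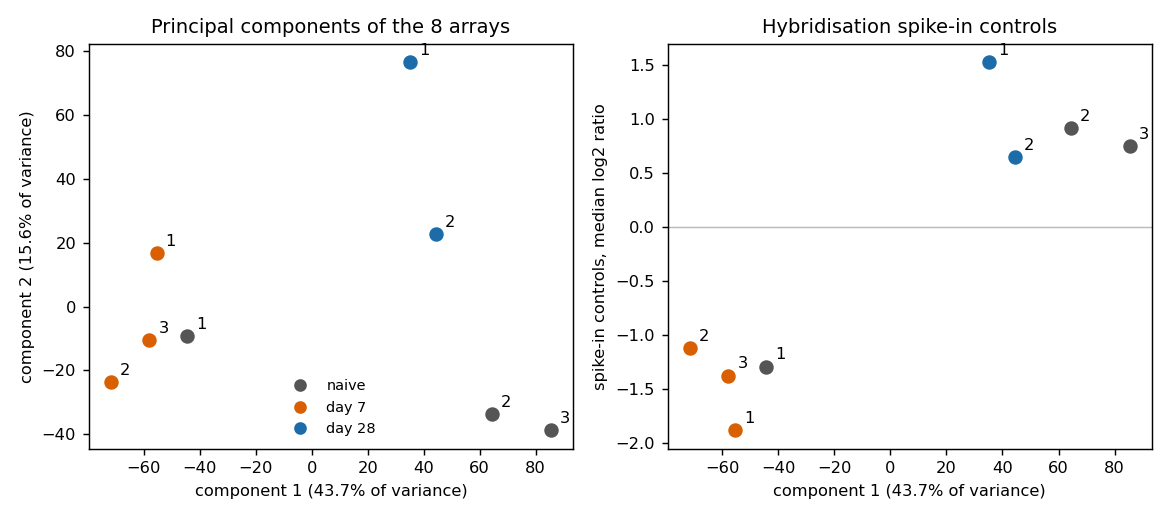
Each point is 1 array, numbered by replicate and coloured by group. The left panel plots principal components 1 and 2 of the log2 ratios, and the right panel plots the median log2 ratio of the 14 spike-in control probe sets against component 1, with naive replicate 1 (-1.29) beside the day 7 arrays.

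The comparison of day 7 with naive arrays asks which genes differed 1 week into the response. Genes of mitosis rose as a group (10 of 28 members, median log2 difference 1.82) and genes of naive and resting T cells fell (1 of 17, median -1.29), both with an adjusted p = 0.0288 with an estimated correlation. Genes of follicular helper T cells (8 of 18 members), of T cell activation (5 of 18) and of DNA replication (3 of 30) rose in camera at its preset correlation, each with an adjusted p = 0.161 with an estimated correlation. Igfbp4, an insulin-like growth factor binding protein abundant in naive T cells, fell 187-fold (log2 difference -7.55 ± 0.32, SE, 3 arrays per group, limma adjusted p = 0.000216, gene ID 16010), or -5.11 on the log2 scale as a mean over its probe sets (adjusted p = 0.000189). Cdk1, the kinase that drives entry into mitosis, rose 18.9-fold (4.24 ± 0.29, adjusted p = 0.00102, gene ID 12534). Cxcr3, a chemokine receptor of effector T cells, rose 26.7-fold (4.74 ± 0.39, adjusted p = 0.00278, gene ID 12766). In total, limma called 103 of 7825 genes, 94 up and 9 down.

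The mitosis list had 28 measured members at day 7. Of these, 10 rose, 0 fell and 18 did not pass; 20 rose adjusted over the list alone. Its median log2 difference was 1.82, with a camera adjusted p = 3.87e-14 and an adjusted p = 0.0288 with an estimated correlation. Ccna2, a mitotic cyclin, rose by 4.06 ± 0.48 on the log2 scale (adjusted p = 0.0119), and Mki67, the Ki-67 proliferation marker, rose by 3.55 ± 0.52 (adjusted p = 0.0285). Of 30 DNA replication genes, 3 rose and 27 did not pass (12 rose adjusted over the list alone; median 1.41, camera adjusted p = 1.91e-06). This call was lost with an adjusted p = 0.161 with an estimated correlation. The 3 were Prim1, a primase subunit (2.76 ± 0.42), Rrm1, a ribonucleotide reductase subunit (2.20 ± 0.34), and Mcm6, a subunit of the replicative helicase (2.10 ± 0.33). As means over their probe sets, Prim1 had 1.86 (adjusted p = 0.0356) and Mcm6 1.78 (adjusted p = 0.0897). Mcm6 did not pass by this measure. Among the low spike-in arrays alone, the medians of day 7 minus naive replicate 1 were 1.65 for mitosis and 0.95 for DNA replication.

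T cell programmes moved at day 7 as follows. Of 18 follicular helper T cell genes, 8 rose and 10 did not pass (15 rose adjusted over the list alone; median 2.80, camera adjusted p = 3.43e-13; adjusted p = 0.161 with an estimated correlation). They included Bcl6, the transcription factor that defines these cells (3.35 ± 0.51, adjusted p = 0.0347), and Cxcr5, their follicle homing receptor (4.35 ± 0.75, adjusted p = 0.0462). Il21, a cytokine that helps B cells, rose by 3.95 ± 0.45 (adjusted p = 0.0102), and the inhibitory receptor Pdcd1 by 4.29 ± 0.66 (adjusted p = 0.0347). Of 18 T cell activation genes, 5 rose and 13 did not pass (8 rose adjusted over the list alone; median 1.58, camera adjusted p = 8.65e-05; adjusted p = 0.161 with an estimated correlation). Cd44, an adhesion receptor of antigen-experienced T cells, rose by 4.45 ± 0.60 (adjusted p = 0.0198), Ctla4 by 3.26 ± 0.50 and Tnfsf11 by 2.62 ± 0.32. Another tested probe set of Cd44 had a log2 difference of 0.68 (adjusted p = 0.386) and did not pass. The mean over the probe sets of Cd44 was 2.57 (adjusted p = 0.0233). Of 17 naive and resting T cell genes, 1 fell, Igfbp4, and 16 did not pass (6 fell adjusted over the list alone; median -1.29, camera adjusted p = 6.81e-09; adjusted p = 0.0288 with an estimated correlation). Ccr7, the lymph node homing receptor, had a log2 difference of -4.53 ± 0.84 (adjusted p = 0.0565) and Il7r, a survival cytokine receptor, of -2.48 ± 0.56 (adjusted p = 0.103). The activation median was 0.88 without day 7 replicate 1. Among the low spike-in arrays alone, the medians were 2.03 for follicular helper, 1.69 for activation and -1.19 for naive and resting genes. The general T cell genes Cd3e (-0.04 ± 1.21, adjusted p = 0.992) and Cd4 (0.30 ± 1.02, adjusted p = 0.9) and the regulatory T cell factor Foxp3 (-0.95 ± 0.60, adjusted p = 0.467) did not pass, nor did Cd8a (0.43 ± 0.50, adjusted p = 0.686).

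B cell genes (18 members, median -0.02, camera adjusted p = 0.498) and MHC class II genes (12 members, median 0.09, camera adjusted p = 0.489) did not pass as groups at day 7. In each, 1 member rose and 0 fell (2 rose adjusted over each list alone). These were the B cell coactivator Pou2af1 (2.77 ± 0.45, adjusted p = 0.0401) and Cd83 (2.87 ± 0.43, adjusted p = 0.0301). Pou2af1, which is also in the follicular helper T cell list, was named after its values were seen. A further 5 lists were called. The Th1 helper list had 11 members, of which 1 rose, Cxcr3 (5 adjusted over the list alone; median 1.86, camera adjusted p = 9.71e-05; adjusted p = 0.143 with an estimated correlation). Ifng, the main Th1 cytokine, had a log2 difference of 4.37 ± 0.87 (adjusted p = 0.0703). Over the 18 alternatives tried, the Th1 median ran from 0.77 to 2.08. The Th17 helper list had 7 members, of which 1 rose, the nuclear receptor Rora (2.82 ± 0.38, or 2.05 as a mean over its probe sets, adjusted p = 0.0262; 4 adjusted over the list alone; median 1.83, camera adjusted p = 0.0162; adjusted p = 0.161 with an estimated correlation). Of 31 oxidative phosphorylation genes 0 passed in limma, and 0 adjusted over the list alone (11 were higher at an unadjusted p under 0.05; median 0.75, camera adjusted p = 0.00746; adjusted p = 0.56 with an estimated correlation). Of 24 interferon response genes and 14 T cell identity genes 0 passed in limma, and 0 adjusted over each list alone (2 and 3 were lower at an unadjusted p under 0.05). Their medians were -0.62 (camera adjusted p = 0.00623) and -0.21 (camera adjusted p = 0.0431), each with an adjusted p = 0.56 with an estimated correlation. Among the low spike-in arrays the medians were 1.84 for Th1, 1.34 for Th17, 0.82 for oxidative phosphorylation, -1.22 for interferon and 0.36 for T cell identity, the last with the opposite sign. Without naive replicate 1 the camera adjusted p was 0.133 for Th17, 0.125 for oxidative phosphorylation and 0.188 for interferon response. Without day 7 replicate 1 it was 0.0980 for oxidative phosphorylation, and for T cell identity it was 0.145 without naive replicate 2, 0.137 without naive replicate 3 and 0.399 without day 7 replicate 2. The T cell identity median turned to 0.07 without naive replicate 2 and 0.20 without day 7 replicate 2, and was -1.07 and -0.53 without naive replicates 1 and 3 and -1.01 and -0.42 without day 7 replicates 1 and 3. That list also lost its call with the spike-in term (camera adjusted p = 0.735), no filter (0.0972), median centring (0.0626) and quantile normalization (0.0514). The interferon medians were 1.20, 0.69 and -0.80 on the naive arrays and 0.07, -0.33 and 0.04 at day 7, so naive replicate 3 lay below every day 7 array. The interferon difference was -0.41, -0.22 and -0.98 without naive replicates 1, 2 and 3 and -0.17 without day 7 replicate 2. The oxidative phosphorylation median was 1.16 without day 7 replicate 2.

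Other large rises at day 7 were those of Plagl1, a zinc finger transcription factor (4.93 ± 0.25, adjusted p = 0.000336), S100a4 (4.83 ± 0.30, adjusted p = 0.000866) and S100a6 (4.36 ± 0.36, adjusted p = 0.00278), both calcium-binding proteins, and Lgals3, which encodes galectin-3 (4.72 ± 0.48, adjusted p = 0.00782). The inflammatory caspase Casp4 rose by 4.90 ± 0.54, Marcksl1 by 4.49 ± 0.80 and Cks2, a partner of cyclin-dependent kinases, by 4.77 ± 0.76. Pclaf, a partner of the replication clamp PCNA, rose by 5.41 ± 0.37 (adjusted p = 0.00102), but a probe set of this gene too dim to be tested had a log2 difference of 0.21. Besides Igfbp4, the 8 other falls were Tdrp (-4.06 ± 0.45), Slfn8 (-3.10 ± 0.33), Selplg (-2.99 ± 0.53), Arhgef18 (-2.76 ± 0.43), Dnm2 (-2.22 ± 0.35), Rcsd1 (-2.19 ± 0.28), Aldh2 (-2.11 ± 0.32) and Rxrb (-1.55 ± 0.26). As means over their probe sets, Marcksl1 had 2.61 (adjusted p = 0.0260) and Dnm2 -1.30 (adjusted p = 0.112). Dnm2 did not pass by this measure. By probe set, 152 of 13042 were called (138 up, 14 down). The number was 1727 without naive replicate 1, 17 without naive replicate 2, 35 without naive replicate 3, 74 without day 7 replicate 2, 18 without day 7 replicate 3, 68 without either day 28 array and 14 with a term for the spike-in split. Of the 35 named genes called, 7 were called with every array left out in turn (Pclaf, Plagl1, S100a4, Cxcr3, S100a6, Igfbp4 and Cdk1), and those called numbered 7 without naive replicate 2, 11 without naive replicate 3, 21, 19 and 9 without day 7 replicates 1, 2 and 3, and 23 without either day 28 array.

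**Figure D2:**
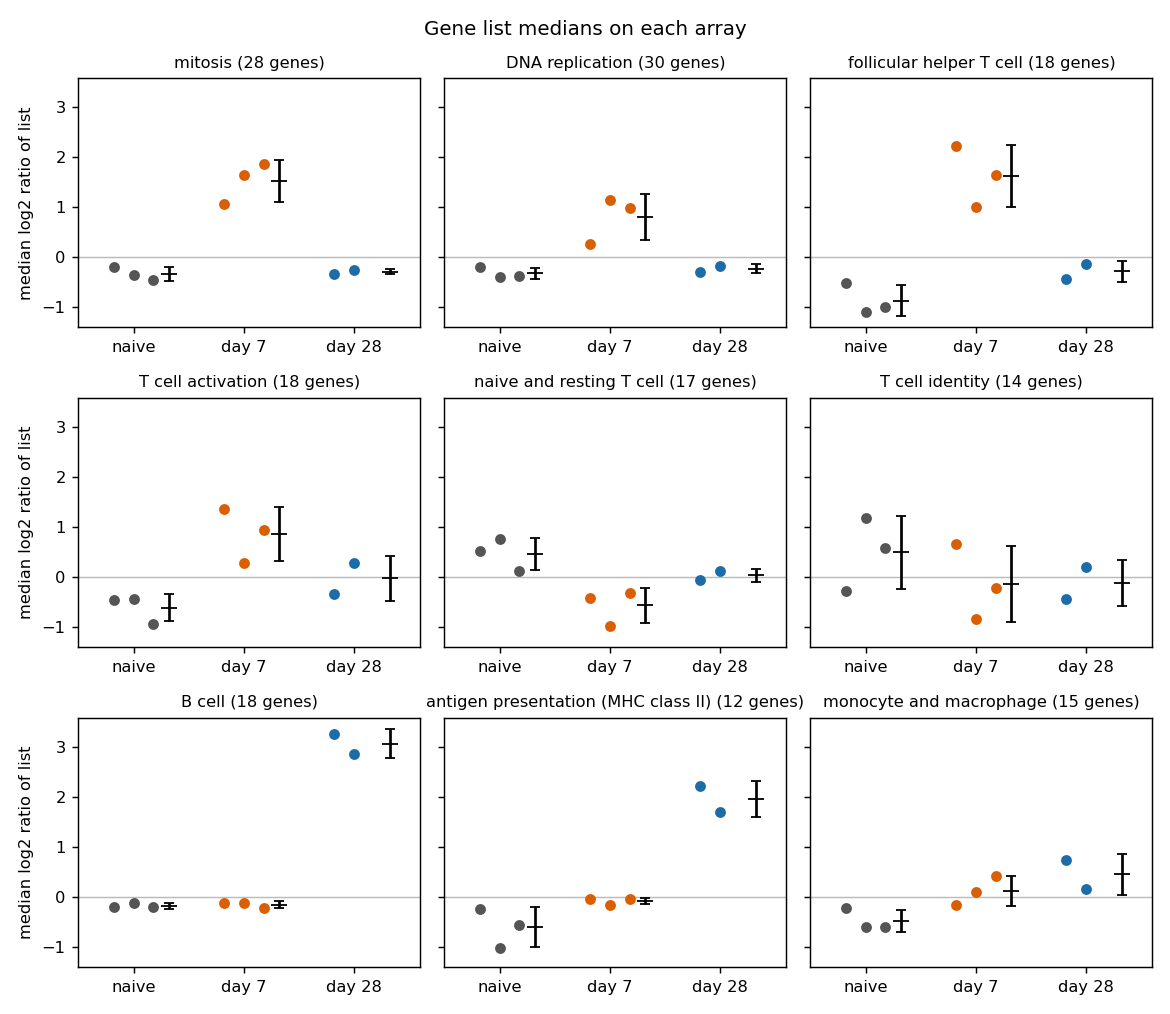
Each panel plots 1 gene list, with 1 point per array for the median log2 ratio of its members and, to the right of each group, the mean of the arrays ± SD (naive and day 7 n = 3, day 28 n = 2). The mitosis medians were 1.06, 1.65 and 1.87 on the day 7 arrays, and the B cell medians were 3.27 and 2.86 on the day 28 arrays.

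The comparison of day 28 with naive arrays asks what differed 4 weeks after immunization. Genes of B cells (10 of 18 members, median log2 difference 3.54) and of antigen presentation on MHC class II (7 of 12, median 2.84) rose. Cd79b, a signalling chain of the B cell receptor, rose 68.3-fold (log2 difference 6.09 ± 0.43, SE, 2 arrays against 3, limma adjusted p = 0.00428, gene ID 15985). Cd74, the invariant chain of MHC class II, rose 195-fold (7.61 ± 0.57, adjusted p = 0.00428, gene ID 16149). Igfbp4 fell 9.34-fold (-3.22 ± 0.36, adjusted p = 0.0154), or -2.36 on the log2 scale as a mean over its probe sets (adjusted p = 0.0167). In total, limma called 33 of 7825 genes, 30 up and 3 down.

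Of 18 measured B cell genes, 10 rose, 0 fell and 8 did not pass at day 28; 16 rose adjusted over the list alone. The median log2 difference was 3.54, with a camera adjusted p = 4.56e-38 and an adjusted p = 0.00244 with an estimated correlation. Ms4a1, which encodes the B cell antigen CD20, rose by 6.74 ± 0.64 (adjusted p = 0.00936), the B cell adaptor Blnk by 4.87 ± 0.31 (adjusted p = 0.00428), the inhibitory receptor Cd22 by 5.55 ± 0.64 (adjusted p = 0.0162), Ly6d by 5.86 ± 0.75 (adjusted p = 0.0262) and Cd24a by 4.17 ± 0.43 (adjusted p = 0.0128). Of 12 MHC class II genes, 7 rose and 5 did not pass (8 rose adjusted over the list alone; median 2.84, camera adjusted p = 9.65e-19; adjusted p = 0.00809 with an estimated correlation). They included the class II chains H2-Eb1 (6.45 ± 0.59, adjusted p = 0.00936), H2-Aa (5.49 ± 0.69, adjusted p = 0.0247) and H2-Ab1 (4.49 ± 0.49, adjusted p = 0.0149), and Cd83 (4.18 ± 0.48, adjusted p = 0.0161). Among the high spike-in arrays alone, the medians of day 28 minus naive replicates 2 and 3 were 3.55 for B cell and 2.91 for class II genes. Outside the lists, Plac8 rose by 5.18 ± 0.58 (adjusted p = 0.0161) and Dda1 fell by 3.14 on the log2 scale (adjusted p = 0.0162). As means over their probe sets, Ms4a1 had 4.31 (adjusted p = 0.0106), H2-Ab1 3.05 (adjusted p = 0.0249), H2-Aa 6.30 (adjusted p = 0.00441), Cd24a 2.39 (adjusted p = 0.0277) and Dda1 -1.70 (adjusted p = 0.0591). Dda1 did not pass by this measure.

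Lists of other cell types had smaller medians at day 28. Of 13 CD8 T cell and cytotoxic genes, 1 rose, the coreceptor chain Cd8b1 (3.70 ± 0.35, adjusted p = 0.00936), and 12 did not pass (4 rose adjusted over the list alone; median 1.09, camera adjusted p = 1.86e-07; adjusted p = 0.157 with an estimated correlation). Cd8a, the other CD8 chain, had a log2 difference of 3.65 ± 0.55 (adjusted p = 0.058). Of 15 monocyte and macrophage genes 0 passed in limma (4 rose adjusted over the list alone and 6 were higher at an unadjusted p under 0.05; median 0.82, camera adjusted p = 4.18e-06; adjusted p = 0.157 with an estimated correlation). The lysozyme gene Lyz2 had a log2 difference of 4.23 ± 0.84 (adjusted p = 0.163). Of 11 NK cell genes 0 passed in limma (3 rose adjusted over the list alone and 3 were higher at an unadjusted p under 0.05; median 0.37, camera adjusted p = 0.00766; adjusted p = 0.157 with an estimated correlation). Of 10 germinal centre B cell and plasma cell genes 0 passed in limma, and 0 adjusted over the list alone (1 was higher at an unadjusted p under 0.05; median 0.84, camera adjusted p = 0.0178; adjusted p = 0.157 with an estimated correlation). Among the high spike-in arrays the medians were 1.16 for CD8, 1.22 for monocyte, 0.48 for NK and 0.95 for germinal centre and plasma cell genes. Cd3e had log2 ratios of -2.43 and 2.68 on the 2 day 28 arrays and Cd4 of -2.43 and 0.42. The differences from naive were -0.17 ± 1.35 for Cd3e and -0.74 ± 1.14 for Cd4, each with an adjusted p = 0.998. The camera adjusted p of the NK list was 0.165 without naive replicate 1 and 0.0549 without naive replicate 2, and that of the germinal centre and plasma cell list was 0.0637 without naive replicate 2 and 0.167 without day 28 replicate 2. The spike-in term, here the same fit as leaving out naive replicate 1, gave the same value for the NK list. The NK median was 0.63 without naive replicate 3 and 0.67 and 0.20 without day 28 replicates 1 and 2. The CD8 median was 1.86 without day 28 replicate 2, the monocyte median 0.48 without day 28 replicate 1 and the germinal centre and plasma cell median 0.39 without naive replicate 3. Over all 18 alternatives, the monocyte median ran from 0.26 to 1.22 and the germinal centre and plasma cell median from 0.12 to 0.95.

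Of the T cell lists called at day 28 against naive, none kept its call with an estimated correlation. T cell activation (18 genes, median 0.80, camera adjusted p = 0.00151; adjusted p = 0.186 with an estimated correlation) and Th1 helper (11 genes, median 0.71, camera adjusted p = 0.00307; adjusted p = 0.157 with an estimated correlation) each had 0 members that passed in limma, over all genes and adjusted over the list alone, and 6 and 3 members higher at an unadjusted p under 0.05. Cd44 had a log2 difference of 2.04 ± 0.67 (adjusted p = 0.567). Of 18 follicular helper T cell genes 0 passed in limma (3 rose adjusted over the list alone and 4 were higher at an unadjusted p under 0.05; median 0.42, camera adjusted p = 0.0046; adjusted p = 0.529 with an estimated correlation). Cxcr5, which B cells also express, had a log2 difference of 3.92 ± 0.84 (adjusted p = 0.203), and Bcl6 of 0.52 ± 0.58 (adjusted p = 0.998). Of 12 regulatory T cell genes 1 rose (3 adjusted over the list alone; median 0.89, camera adjusted p = 0.00151; adjusted p = 0.157 with an estimated correlation). That gene was Swap70 (3.94 ± 0.44, adjusted p = 0.0154), which is best known from B cells, while Foxp3 had a log2 difference of -0.81 ± 0.67 (adjusted p = 0.998). Of 17 naive and resting T cell genes 1 fell, Igfbp4 (4 fell and 2 rose adjusted over the list alone; median -1.14, camera adjusted p = 0.0473; adjusted p = 0.186 with an estimated correlation). Il7r (-2.07 ± 0.63, adjusted p = 0.51) and Ccr7 (-2.97 ± 0.94, adjusted p = 0.551) did not pass. Of 24 interferon response genes (median -0.54, camera adjusted p = 0.0122; adjusted p = 0.72 with an estimated correlation) and 14 cholesterol synthesis genes (median -0.55, camera adjusted p = 0.0273; adjusted p = 0.157 with an estimated correlation) 0 passed in limma, over all genes and adjusted over each list alone, and 1 and 2 were lower at an unadjusted p under 0.05. Among the high spike-in arrays the medians were 0.89 for activation, 0.77 for Th1, 0.65 for follicular helper, 1.10 for regulatory, -0.72 for naive and resting, -0.41 for interferon and -0.56 for cholesterol genes. Mki67 (1.69 ± 0.58, adjusted p = 0.616) and the mitosis list (28 genes, median 0.13, camera adjusted p = 0.513) did not pass.

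Calls of these lists depended on single arrays. Without naive replicate 2 the camera adjusted p was 0.0589 for follicular helper, 0.195 for interferon and 0.220 for naive and resting T cell genes. Without day 28 replicate 2 it was 0.217 for T cell activation, 0.167 for follicular helper, 0.0927 for Th1, 0.0590 for regulatory T cell, 0.111 for interferon and 0.0610 for naive and resting genes. Without naive replicate 1 it was 0.0629 for cholesterol synthesis and 0.170 for interferon genes, and without naive replicate 3 it was 0.0993 for both cholesterol synthesis and naive and resting genes. Without day 28 replicate 1 it was 0.105 for cholesterol synthesis and 0.295 for naive and resting genes. The spike-in term, here the same fit as leaving out naive replicate 1, gave the same values for cholesterol synthesis and interferon genes. The interferon median was -0.80 on naive replicate 3, below both day 28 arrays (-0.06 and -0.32), and the difference was -1.47 without that array. The naive and resting median was -0.72 without naive replicate 1 and -0.50 without day 28 replicate 1, and the activation median 0.44 without day 28 replicate 2. The follicular helper median was 0.65 and 0.21 without naive replicates 1 and 2 and 0.12 without day 28 replicate 2. Cholesterol synthesis also lost its call with array weights (camera adjusted p = 0.0585) and with means of probe sets (0.0730). Naive and resting genes lost theirs with 5 other alternatives (0.0526 to 0.107). At an unadjusted p under 0.05 in limma lay 827 probe sets (6.3%). Chance alone gives 5%, which is more than the 613 with only the 5 arrays compared. By probe set, limma called 42 of 13042 (35 up, 7 down). The number was 20 without naive replicate 2, 7 without naive replicate 3, 27 without day 7 replicate 2, 14 without day 7 replicate 3 and 2 without day 28 replicate 1, and it was 0 in limma with only the 5 arrays compared (613 at an unadjusted p under 0.05). Of the 16 named genes called, Blnk was called with every array left out in turn, and those called numbered 11 without naive replicate 2, 3 without naive replicate 3, 13, 14 and 7 without day 7 replicates 1, 2 and 3, and 1 and 12 without day 28 replicates 1 and 2.

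The comparison of day 28 with day 7 asks what differed between the later and the earlier time. Genes of B cells (12 of 18 members) and of MHC class II (6 of 12) rose, and genes of mitosis (8 of 28) fell. Cd79b rose 99.1-fold (log2 difference 6.63 ± 0.43, SE, 2 arrays against 3, limma adjusted p = 0.00256), and Blnk rose 24.7-fold (4.62 ± 0.31, adjusted p = 0.00256). Plagl1 fell 29.6-fold (-4.89 ± 0.28, adjusted p = 0.00251), and Cdk1 fell 10.4-fold (-3.37 ± 0.33, adjusted p = 0.00639). In total, limma called 118 of 7825 genes, 39 up and 79 down. All day 7 arrays were low spike-in arrays and both day 28 arrays were high ones, so no shift inside either set exists for this comparison.

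Of 18 B cell genes, 12 rose and 6 did not pass at day 28 against day 7; 16 rose adjusted over the list alone (median 3.45, camera adjusted p = 3.51e-25; adjusted p = 0.00669 with an estimated correlation). Ms4a1 rose by 5.91 ± 0.64, Ly6d by 5.33 ± 0.75, Tnfrsf13c, the receptor for the B cell survival factor BAFF, by 5.33 ± 0.58, Cd72 by 4.53 ± 0.60, Fcer2a by 4.45 ± 0.57 and Cd24a by 4.15 ± 0.43. Of 12 MHC class II genes, 6 rose and 6 did not pass (8 rose adjusted over the list alone; median 2.35, camera adjusted p = 3.26e-13; adjusted p = 0.0186 with an estimated correlation), among them Cd74 (5.79 ± 0.57), H2-Eb1 (5.48 ± 0.59), H2-Aa (4.34 ± 0.69), H2-Ab1 (4.26 ± 0.49) and the costimulatory receptor Cd40 (2.49 ± 0.35). As means over their probe sets, Ms4a1 had 4.20 (adjusted p = 0.00740), Cd24a 2.48 (adjusted p = 0.0144), H2-Aa 5.34 (adjusted p = 0.00644) and H2-Ab1 3.22 (adjusted p = 0.0126). Of 13 CD8 T cell and cytotoxic genes, 2 rose, Cd8b1 (3.87 ± 0.35, adjusted p = 0.00559) and Cd8a (3.22 ± 0.55, adjusted p = 0.0433), and 11 did not pass (3 rose adjusted over the list alone; median 0.71, camera adjusted p = 0.0435; adjusted p = 0.43 with an estimated correlation). That list's camera adjusted p was 0.0538 without naive replicate 1, 0.357 without day 7 replicate 1 and 0.0737 without day 28 replicate 1, with medians of 0.71, 0.37 and 0.31. It was 0.162 with the spike-in term (median 0.32), 0.111 with array weights (0.29), 0.170 with no filter (0.04) and 0.0546 with quantile normalization (0.92). Of 17 naive and resting T cell genes, 2 rose and 15 did not pass (3 rose adjusted over the list alone; median 0.43, camera adjusted p = 4.55e-05; adjusted p = 0.0508 with an estimated correlation). They were Igfbp4 (4.32 ± 0.36, adjusted p = 0.00351; 2.75 as a mean over its probe sets, adjusted p = 0.00644) and Cd55, a regulator of complement (2.56 ± 0.42, adjusted p = 0.0379). As a mean over its probe sets, Cd55 had 2.34 (adjusted p = 0.0522) and did not pass. With a term for the spike-in split, that list's camera adjusted p was 0.462.

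Of 28 mitosis genes, 8 fell and 20 did not pass at day 28 against day 7; 15 fell adjusted over the list alone (median -1.69, camera adjusted p = 1.71e-12; adjusted p = 0.0276 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, had a log2 difference of -4.45 ± 0.60, Cenpa, the centromeric histone, of -3.45 ± 0.35 and Nusap1 of -2.82 ± 0.39, and all 3 fell. Of 30 DNA replication genes, 2 fell, Mcm6 (-2.85 ± 0.36) and Rrm1 (-2.11 ± 0.38), and 28 did not pass (8 fell adjusted over the list alone; median -1.39, camera adjusted p = 3.7e-05; adjusted p = 0.213 with an estimated correlation). Of 18 follicular helper genes, 2 fell, Il21 (-3.94 ± 0.50, adjusted p = 0.0162) and Gpm6b (-3.14 ± 0.36, adjusted p = 0.0116), and 16 did not pass (13 fell adjusted over the list alone; median -1.83, camera adjusted p = 3.43e-07; adjusted p = 0.332 with an estimated correlation). Bcl6 had a log2 difference of -2.83 ± 0.58 (adjusted p = 0.0648). Other large falls were Pclaf (-5.27 ± 0.42), Cks1b (-5.12 ± 0.73), Nudt1 (-4.64 ± 0.82), Cd160 (-4.25 ± 0.33), Gna13 (-3.90 ± 0.36), Lims1 (-3.80 ± 0.66) and Ptger2, a prostaglandin E receptor (-3.78 ± 0.28); the dim probe set of Pclaf had a difference of -0.29. As means over their probe sets, Cdc20 had -2.69 (adjusted p = 0.0272), Cks1b -3.85 (adjusted p = 0.0124), Mcm6 -1.90 (adjusted p = 0.0985), Cd160 -2.02 (adjusted p = 0.0291), Gna13 -2.31 (adjusted p = 0.0772) and Lims1 -1.80 (adjusted p = 0.105). Mcm6, Gna13 and Lims1 did not pass by this measure. Cd44 (-2.41 ± 0.67, adjusted p = 0.139) and Mki67 (-1.86 ± 0.58, adjusted p = 0.174) did not pass.

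3 metabolic and ribosomal lists were called at day 28 against day 7 with 0 of their members past the threshold in limma. They were oxidative phosphorylation (31 genes; 5 fell adjusted over the list alone and 12 were lower at an unadjusted p under 0.05; median -1.03, camera adjusted p = 0.00539; adjusted p = 0.43 with an estimated correlation) and cholesterol synthesis (14 genes; 4 fell adjusted over the list alone and 4 were lower at an unadjusted p under 0.05; median -0.72, camera adjusted p = 0.019; adjusted p = 0.194 with an estimated correlation). The other was the cytosolic ribosome (20 genes; 0 adjusted over the list alone, with 1 higher and 1 lower at an unadjusted p under 0.05; median 0.75, camera adjusted p = 0.0153; adjusted p = 0.506 with an estimated correlation). Without day 7 replicate 1 the camera adjusted p was 0.0995 for oxidative phosphorylation. Without day 7 replicate 2 it was 0.0590 for cholesterol synthesis and 0.170 for the ribosome, and without day 28 replicate 1 it was 0.118 and 0.0654. The ribosome median was 1.38 and 0.16 without day 7 replicates 1 and 2 and 0.43 without day 28 replicate 1. With the spike-in term it was 0.01 with the camera direction turned (camera adjusted p = 0.997), and with array weights its camera adjusted p was 0.0680. On single arrays it was 0.37, -1.71 and -0.32 at day 7 and 0.19 and 0.01 at day 28. The cholesterol synthesis median was -1.13 without day 28 replicate 2, and its camera adjusted p was 0.0567 with the stricter filter. By probe set, limma called 170 of 13042 (55 up, 115 down). The number was 810 without naive replicate 1, 76 without naive replicate 2, 100, 54 and 25 without day 7 replicates 1, 2 and 3, 29 and 74 without day 28 replicates 1 and 2, and 0 in limma with a term for the spike-in split (1402 at an unadjusted p under 0.05). Of the 33 named genes called, 8 were called with every array left out in turn (Cd79b, Blnk, Pclaf, Plagl1, Cd160, Ptger2, Cd8b1 and Igfbp4), and those called numbered 23 and 29 without naive replicates 2 and 3, 24, 19 and 15 without day 7 replicates 1, 2 and 3, and 10 and 22 without day 28 replicates 1 and 2.

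Across the 3 stages, the calls sorted genes into time courses. A transient rise, higher at day 7 than both naive and day 28, was called for 47 genes, among them Cdk1, Plagl1, Il21 and Pclaf, and a transient fall for 3 genes, Igfbp4, Aldh2 and Rcsd1. A late rise, at day 28 over both other stages, was called for 24 genes, among them Cd79b, Cd74, Ms4a1, Blnk and Cd8b1. A late fall was called for Tspo, a protein of the outer mitochondrial membrane, a sustained rise for Cd83 and a sustained fall for 0 genes in limma (75 at an unadjusted p under 0.05). Tspo was named because its count was 1, after its values were seen. Igfbp4 had mean log2 ratios of 3.22 ± 0.49 (SD) in naive, -4.32 ± 0.15 at day 7 and 0.00 ± 0.06 at day 28. Against naive, Cd83 and S100a4 rose and Igfbp4 fell at both times, and 0 genes were called in opposite directions in limma (28 at an unadjusted p under 0.05). Unrelated calls of these numbers would share 0.360 rising and 0.00345 falling genes, figures that leave the shared naive arrays out of account. In 100 simulations of unchanged groups that shared their naive arrays, a mean of 0 genes were shared. Unchanged groups give almost no calls, so this number could hardly differ. Neither figure can tell whether the overlap exceeds what the shared arrays produce. Across genes, which are not independent replicates, the differences at day 7 and day 28 correlated at r = 0.273, below the mean of 0.447 that the shared naive arrays alone gave in simulation. The covariance was 0.219 against a simulated mean of 0.205 and a highest of 0.222.

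The numbers of shared genes and time courses rested on single arrays. The 3 genes shared by both times became 26 without naive replicate 1, 1 without naive replicate 2, naive replicate 3 or day 28 replicate 2, and 0 in limma without day 7 replicate 3 or day 28 replicate 1 (99 and 111 at an unadjusted p under 0.05). The 47 transient rises became 424, 8 and 14 without naive replicates 1, 2 and 3, 19 and 7 without day 7 replicates 2 and 3, and 5 and 9 without day 28 replicates 1 and 2. The 24 late rises became 13 and 4 without naive replicates 2 and 3, 15, 14 and 8 without day 7 replicates 1, 2 and 3, and 2 without day 28 replicate 1. With a term for the spike-in split, limma called 0 transient and 0 late rises (142 and 266 at an unadjusted p under 0.05). Without single arrays, the 3 transient falls became 1 to 18, the sustained rise, Cd83, 0 to 17 and the late fall, Tspo, 0 to 4; 0 was counted for Cd83 without naive replicate 2, naive replicate 3, day 7 replicate 3 or either day 28 array.

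**Figure D3:**
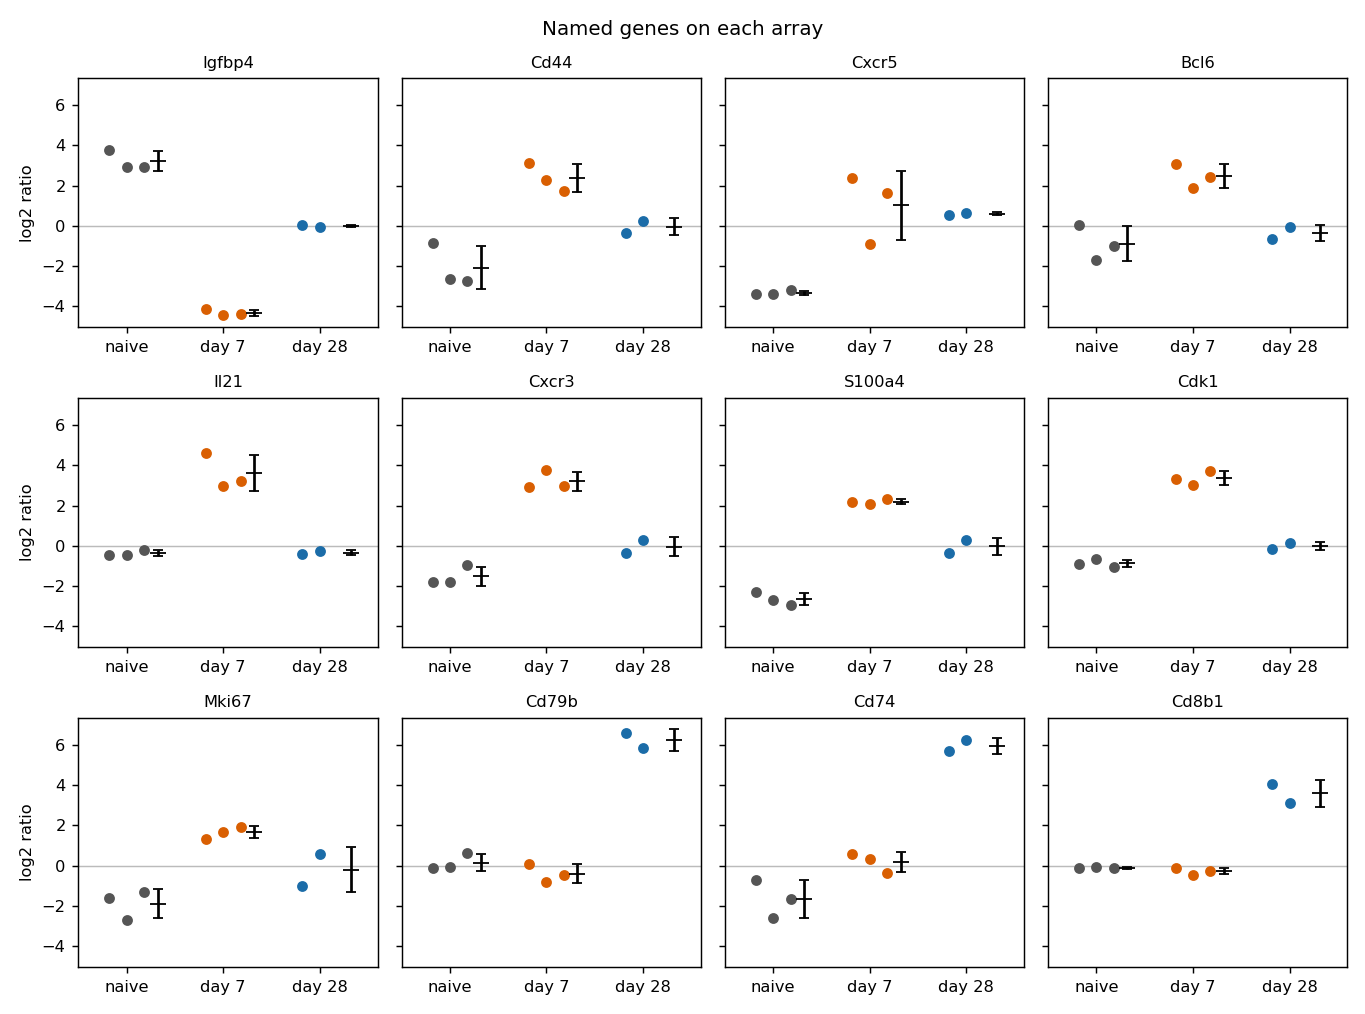
Each panel plots the log2 ratio of 1 named gene, with 1 point per array and, to the right of each group, the mean ± SD (naive and day 7 n = 3, day 28 n = 2). Igfbp4 lay between 2.92 and 3.79 on the naive arrays and between -4.43 and -4.15 at day 7, and Cd79b lay at 6.61 and 5.84 on the day 28 arrays.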

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

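Of the tests weighed here, those on naive replicate 1, on the B cell genes, and on batch and sex for the mitosis genes were chosen after the result was seen; the count of other splits was planned. The hybridisation spike-in controls, which no comparison used, had their highest median on day 28 replicate 1, at a log2 ratio of 1.53, above all 3 naive arrays (-1.29, 0.92 and 0.75). Of the 10 lists called at day 28 against day 7, 4 had camera directions against naive that differed between the times. Against naive, none of these 4 passed at both times: the B cell list had a median of -0.02 at day 7 (camera adjusted p = 0.498), and the cytosolic ribosome passed at neither. The differences, as medians of day 28 minus day 7, were -1.03 for oxidative phosphorylation (adjusted p = 0.00539), -0.72 for cholesterol synthesis (adjusted p = 0.019), 0.75 for the cytosolic ribosome (adjusted p = 0.0153) and 3.45 for B cell genes (adjusted p = 3.51e-25). With an estimated correlation, their adjusted p were 0.43, 0.194, 0.506 and 0.00669.

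Naive replicate 1 stood apart from the other naive arrays on the first component. A mislabelled day 7 array was argued against by the mitosis list, where this array lay at 0.0152 on a scale from the other naive arrays (0) to the day 7 arrays (1), with a median gap to day 7 of 1.65. A labelling or hybridisation batch shared with the day 7 arrays stays open and may account for it. Over 12792 probe sets called in no comparison, its difference from the other naive arrays correlated at r = 0.478, across probe sets that are not independent, with the difference of day 7 from day 28 arrays. A different sex of the animal, on which the labels are silent, was not tested and stays open: the Y-linked gene Eif2s3y had log2 ratios of 2.87 on this array and -0.04 and 0.24 on the other naive arrays, and Kdm5d, also Y-linked, had 3.35 by 1 dim probe set against -0.59 and -0.66, while Xist was low on it and on naive replicate 2 (-5.25 and -5.58).

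The B cell genes at day 28 stood far above those of other cell types. A lower share of the main cell type that raised all other types alike was argued against by a difference of 3.12 in median shift. It lay between 18 B cell genes (3.54) and 58 genes of 7 other lists (0.41). Those lists were neutrophil, erythroid and platelet, stroma and endothelium, dendritic cell, NK, monocyte and CD8. Their own medians ran from -0.06 for dendritic cell to 1.09 for CD8 genes. The permutation p = 1e-05 (two-sided, the smallest that 100000 resamples give) shuffled genes, which are not independent. It does not take into account that the B cell list was chosen after its shift was seen. A lower share that let in mostly B cells would raise B cell genes most, so this test cannot weigh it. A labelling or hybridisation batch that follows the spike-in split was argued against, as the whole cause, by a median shift of 3.55 inside the high spike-in arrays (lower quartile 2.48). A batch of the day 28 arrays alone cannot be told apart from the time. B cells among the sorted day 28 cells may be the source. Of 24 B cell genes that none of the lists hold, written down after the other results were seen, 17 were measured. Their median shift was 2.35 (quartiles 0.87 and 3.76). Of them, 2 passed the threshold and 11 were higher on both day 28 arrays than on all naive arrays. The filter asks for a ratio of at least 1 on 2 arrays, which the 2 day 28 arrays alone can supply, so it favours genes that rose there. Cd79b (6.61 and 5.84), Cd74 (5.67 and 6.23) and Ms4a1 (6.87 and 5.20) were high on both day 28 arrays. They were named by a rule that asks for groups without overlap, so this was fixed beforehand and adds no support. The labels do not name the sorted population, so whether the gate excluded or selected B cells is unknown, and the time after immunization remains open as an untested biological cause.

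The mitosis genes at day 7 were higher than in naive cells. A labelling or hybridisation batch cannot be told apart from the time: inside the low spike-in arrays the median shift was 1.65 (lower quartile 1.04 over genes), but that set holds a single naive array. A different sex of the animals cannot be told apart either: arrays with more and less Xist signal inside naive and day 28 differed by a median of -0.0054 on this list, but the side with more signal holds 1 array in each group, and Xist and Eif2s3y did not divide the arrays alike. The 6 naive and day 7 arrays allow 10 splits, too few for a share under 0.05; the real split gave 152 probe sets and the highest of the others 0. Cell division in response to the immunization stays open beside them.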

How the results depend on the processing

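The term for the spike-in split, the replacement filters and the rule for a gene's probe set were chosen after seeing the data. The other alternatives were planned. Probe sets called, for day 7 against naive, day 28 against naive and day 28 against day 7 (152, 42 and 170), were 76, 26 and 62 with the stricter filter, 54, 19 and 52 with trended and robust variance, 31, 13 and 28 at adjusted p under 0.01, and 94 with no filter for the first. With only the groups compared they were 68, 0 in limma (613 at an unadjusted p under 0.05, fewer than chance alone gives) and 591. Array weights, whose fit did not fully converge, gave day 7 replicate 3 a weight of 9.50, against 0.29 to 1.74 on the other arrays. Weighted so, probe sets called were 2935 and 1562 for the first and last. With the spike-in split as a term they were 14 and, in limma, 0 (1402 at an unadjusted p under 0.05) for the first and last. Day 7 and day 28 arrays lie wholly on different sides of that split, and fewer degrees of freedom are left. On its low side lies a single naive array, naive replicate 1, on which the first count rests. Leaving out single arrays gave 17 to 1727, 2 to 57 and 25 to 810. All 152 and 170 calls were kept without naive replicate 1. Beyond these values, the cause was not tested. A replicate block gave 16, 9 and 15, but no label says that equal numbers pair the samples. Correlations of deviations from the group means ran from -0.36 to 0.17 between arrays with the same number. With other numbers they ran from -0.19 to 0.35. They cannot decide on pairing, since the deviations of the 2 day 28 arrays mirror each other.

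List calls (10, 13 and 10) were 2, 2 and 3 with an estimated correlation. For day 28 against naive they were 4 by fry and 8 to 15 without single arrays, with 8 without naive replicate 2 or day 28 replicate 2. Apart from these tests, 6, 4 and 5 lists were called under all 18 alternatives: at day 7 naive and resting, activation, follicular helper, Th1, DNA replication and mitosis; at day 28 against naive CD8, B cell, MHC class II and monocyte; at day 28 against day 7 follicular helper, DNA replication, mitosis, B cell and MHC class II. At day 28 against naive, the spike-in term and leaving out naive replicate 1 are the same fit among these 18. With the spike-in split as a term, the median of T cell identity turned to 0.36 at day 7 against naive. At day 28 against day 7 its median went from -0.18 to -0.93 and only its camera direction turned, as did that of the cytosolic ribosome, with a median of 0.014 (the cause was not tested). Genes shared by both times (3) were 0 with trended and robust variance, with only the groups compared or with a replicate block (147, 122 and 139 at an unadjusted p under 0.05), 19 with array weights and 0 to 26 without single arrays. Transient rises (47) were 17 with the stricter filter, 8 with trended variance, 656 with array weights, 4 with a replicate block, 0 with the split and 5 to 424 without single arrays. Late rises (24) were 15, 11, 0 with only the groups compared, 5 with a replicate block, 0 with the split and 2 to 27. At unadjusted p under 0.05 the 0s were 142, 101 and 266. Quantile normalization and median centring, which move the median of all differences from 0.11, -0.05 and -0.16 towards 0, kept the total count of probe sets in each comparison within 1.5 times. With quantile normalization the falls at day 28 against naive (7) were 4 and the rises at day 28 against day 7 (55) were 83, and transient falls (3) were 10, or 7 with median centring. Of the list values 1635 stayed on their side of the threshold, 61 passed it, 95 lost it and 3 reversed; of the named genes' values 2597 stayed, 100 passed and 502 lost it, with 0 reversed. The probe sets near background limit what can be read from folds.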

Other observations

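The comparisons and lists below were planned before the data were examined. Several groups of genes had single members that changed while their list did not pass. In the endoplasmic reticulum stress and secretion list (23 genes), Dnajc3, a chaperone partner of the secretory pathway, rose at day 7 against naive (log2 difference 2.23) and fell at day 28 against day 7 (-2.37). The list medians were 0.70 at day 7 and 0.12 at day 28 against naive, and -0.59 between them (camera adjusted p = 0.0502, 0.0795 and 0.55). In glycolysis (14 genes), Tpi1, triosephosphate isomerase, did the same (3.20 and -3.71), with list medians of 0.40, -0.20 and -0.86 (camera adjusted p = 0.221, 0.333 and 0.0543). In the Th2 helper list (6 genes), the cytokine Il4 rose at day 7 (4.16). Il4 is also in the follicular helper T cell list, which was called at day 7. The Th2 helper medians were 0.62, 0.17 and -0.75 (camera adjusted p = 0.336, 0.613 and 0.55). Among 17 migration receptors, 3 rose at day 7 (Cd44, Cxcr3 and Cxcr5) and 1 fell (Selplg, the P-selectin ligand). The list medians were 0.19, 0.29 and 0.10 (camera adjusted p = 0.953, 0.0503 and 0.223), and 16 of its members are also in other lists. At day 28 against naive Ccr6, a chemokine receptor of B cells and Th17 cells, rose (4.36). Dnajc3, Tpi1, Il4 and Ccr6 were named here after their values were seen.

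Lists of other processes passed in none of the 3 comparisons. Medians, for day 7 against naive, day 28 against naive and day 28 against day 7, were 0.36, 0.01 and -0.43 for 18 immediate early genes (camera adjusted p = 0.228, 0.979 and 0.367), 0.17, -0.21 and -0.27 for 9 heat shock genes (0.506, 0.773 and 0.688), -0.09, -0.40 and 0.03 for 20 nucleolus and ribosome biogenesis genes (0.162, 0.563 and 0.378) and 0.50, 0.06 and -0.35 for 19 apoptosis regulators (0.221, 0.513 and 0.595). Among markers of other cell types, medians were -0.33, -0.06 and 0.28 for 8 dendritic cell genes (0.177, 0.946 and 0.126), 0.64, 0.49 and -0.16 for 7 neutrophil genes (0.463, 0.294 and 0.817) and -0.25, 0.27 and 0.50 for 5 erythroid and platelet genes (0.162, 0.513 and 0.0725). The 4 stroma and endothelium genes, too few to test, had medians of 0.06, 0.27 and 0.33. Nkg7 and Cd160, genes of cytotoxic and NK cells, rose at day 7 against naive (4.05 and 4.22), and Cd160 fell at day 28 against day 7 (-4.25). Nrp1, a regulatory T cell marker, rose at day 7 (4.06). Nkg7, Cd160 and Nrp1 were named at day 7 after their values were seen.

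Per array, 18S ribosomal RNA controls had log2 ratios of -4.19, 1.13 and 1.21 on the naive arrays, -4.51, -1.78 and 0.77 at day 7 and -2.53 and 2.97 at day 28. The difference between 3' and 5' probe sets of beta-actin, relative between arrays as for Gapdh, was 0.93, 0.05 and -0.01, then -0.42, 1.27 and 2.76, then -1.08 and -0.05. For the named genes called that had other kept probe sets (27 results, 50 probe sets), 49 of the other probe sets moved in the same direction and 16 passed the threshold.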
